A study of Caenorhabditis elegans with 2 samples.

How the data were processed

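Binding of LIN-35, the single retinoblastoma-family pocket protein of Caenorhabditis elegans and a subunit of the DREAM complex, was profiled by ChIP-seq in whole young adult worms of both sexes. Per the labels, the 2 samples are biological replicates 1 and 2 of 1 group, chromatin was fragmented by sonication, and the antibody is listed as directed against LIN-35. The strain carries an integrated transgene in which the promoter of pie-1 drives LIN-35 fused to GFP and FLAG, followed by the 3' untranslated region of puf-5, with an unc-119 rescue gene. The pie-1 promoter and the puf-5 3' untranslated region are germline regulatory sequences, and the labels do not say how much of the recovered LIN-35 was the transgenic or the endogenous protein.

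For each of the builds ce10 and ce11 the authors deposited 4 peak lists: a relaxed list of peaks and background for each replicate, a relaxed list from the alignments of both replicates pooled, and a list thresholded by irreproducible discovery rate. Per the deposited text indexes, each relaxed list was made from treatment alignments and a control, and the thresholded list was derived from the pooled and replicate lists. The aligner, the peak caller and their versions are not given in the sources used here, and the control was not analysed here. The signal value of each peak is the one the authors deposited; its scale is not stated, so it was used only to rank and describe peaks within a list. The authors deposited the q-value of each peak as −log10; it is 3.78 for every peak of the thresholded ce11 list and was not used for ranking. Read numbers were not analysed here, so the depth of each library is unknown and no interval given covers it.

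The ce11 lists were the main lists. No peak extends past the chromosome ends of the WBcel235 reference, the same assembly as ce11, and gene positions came from Ensembl release 115. Coordinates are 1-based in ce11, and no coordinate was converted between builds. A coding gene was called bound when a thresholded summit lay within 500 bp of its annotated 5' end. Divergent genes that share a summit within that distance were therefore both bound. Genes transcribed from an upstream promoter of an operon were bound only where a summit lay within 500 bp of their own 5' end. Annotated 5' ends of worm genes often mark the trans-splice site or start codon rather than the start of transcription.

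Replicates were compared by cutting both replicate lists to the 2712 strongest peaks, the length of the thresholded list, and counting summits within 200 bp of each other. Summits were placed at random within their chromosome 1000 times for the replicate agreement and the promoter share, which gives one-sided p-values. Spearman's rank correlation was computed across peaks, which are not independent replicates, with 1000 bootstrap resamples. The 22 gene lists were compared with all other coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. Genes, not samples, are the units of these tests, so their p-values do not measure variation between animals. Motifs were searched on both strands of windows of 100 bp on each side of summits at gene 5' ends, against 1 window per summit at a random unbound gene of the same chromosome, at the same offset from the 5' end. The E2F site and the CHR element were also run reversed, which keeps their base composition; the GAGA repeat and the E-box were not. Shares are given with 95% Wilson intervals, and an upper limit for a count of 0 is 3 counts of the total; both cover counting error only.

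The gene lists, motifs, thresholds and the rule for named genes were fixed before the data were examined. Named genes were those with a 5' end within 500 bp of the 20 strongest peaks found in each replicate list, all members of the DREAM complex and transgene lists, up to 4 bound members of highest signal in each list past an adjusted p of 0.05, and up to 2 in the others. Some are given as counts only. Listed symbols that the annotation does not use were left out, 1 from the DNA replication list and 1 from the P granule and small RNA list. The alternatives tried were ce10, the 1356 strongest peaks, merged overlapping peaks, each replicate alone, distances of 200 and 1000 bp, the nearest 5' end only, an autosomal background, other summit distances and list lengths, other control windows and narrower windows of 50 bp on each side. Nuclear peaks only, the 1000 or 200 strongest peaks, peaks among the strongest of both replicates, and windows without ribosomal protein promoters were added after seeing the data.

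The tests were checked on simulated data. Among 200 random lists of 30 genes each, drawn from 19973 coding genes, 4% passed an unadjusted p of 0.05 when no enrichment was planted, 47% when 2-fold enrichment was planted and 98% when 4-fold was planted. Bound genes were drawn independently there, so the check does not cover summits shared by neighbouring genes or lists of clustered genes. A motif planted in 20% of 1000 windows was recovered as a difference of 16.7 percentage points, and agreement of 60% planted between 2 lists of 2000 peaks was recovered as 60.4%. The result for 1 bound gene is not reported here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.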

Results

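LIN-35 ChIP-seq in young adult worms gave 2712 peaks past the authors' irreproducible discovery rate threshold in ce11. These were exactly the 2712 strongest of the 30000 peaks in the pooled relaxed list, with a median width of 296 bp and signals from 41.9 to 8256. The replicate lists held 30000 and 26192 peaks. The study has 1 group of 2 biological replicates, so the comparisons are between the replicates, between parts of the genome and between groups of genes.

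Of the 20 strongest peaks found in each replicate list, 8 were on the mitochondrial genome and 12 were nuclear, 4 of them upstream of ribosomal protein genes. The strongest nuclear peak was 276 bp upstream of rpl-3, a large ribosomal subunit gene, at chromosome III 3867306 to 3867778, with a signal of 2773 and rank 4 in both replicates. It was followed by peaks at cdc-48.1, which encodes a p97-type AAA ATPase (chromosome II 10563375 to 10563781, signal 2066), at tasp-1 (chromosome III 10759044 to 10759425, signal 1679) and at rpl-35 (chromosome III 7854517 to 7854862, signal 1526). Peaks with signals from 793 to 1120 lay at rpl-20 and its divergent neighbour Y17G9B.5, sec-61.G of the translocon, cox-5A of cytochrome c oxidase, eelo-2, rpl-15 with K11H12.8, Y39B6A.43 and the mitochondrial import gene ddp-1. All of these summits were intergenic. The remaining nuclear peak of the 12, at chromosome X 11093893 to 11094530 (signal 849), had no coding 5' end within 500 bp.

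The strongest peaks of the replicates overlapped in part. Of the 2712 strongest peaks of replicate 1, 1490 (54.9%, 95% interval 53.1 to 56.8) had a summit within 200 bp of one of the 2712 strongest of replicate 2, against a mean of 1.64% and a maximum of 2.29% over random placements (permutation p = 0.000999, the smallest that 1000 placements can give). With both lists cut to their 1356 strongest peaks the share was 63.7%, and at 200 it was 78.5%. Of the thresholded peaks, 2551 (94.1%) had a summit somewhere in both replicate lists, and 1445 (53.3%) among the 2712 strongest of both. The 94.1% was counted against the full relaxed lists, and no random level is given for it. The 53.3% depended on signal: it was 97.1%, 73.0%, 33.9% and 9.14% in successive groups of 678 peaks, strongest first. Most of the weaker peaks, and genes bound only through them, thus lacked such support in both replicates. Across those 2551 peaks, Spearman's rho between the replicates' signals was 0.536 (95% bootstrap interval 0.507 to 0.567). The thresholded list was built from both replicates, so its values are not an independent test of it.

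**Figure D1:**
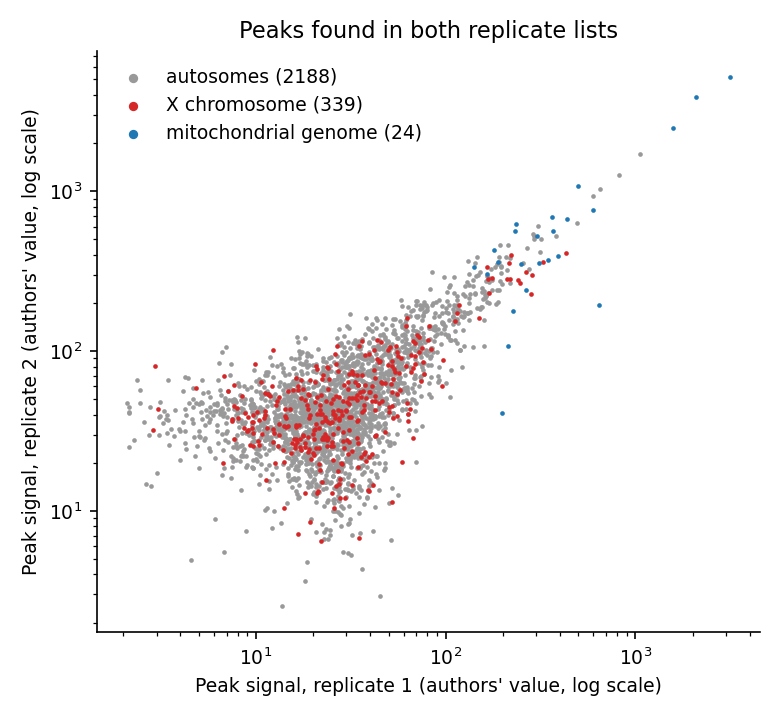
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), both as the authors' values on log scales, for the 2551 thresholded peaks with a summit in both replicate lists; each point is a peak, coloured by autosomes, X chromosome or mitochondrial genome. The rank correlation over all of them is 0.536.

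Summits concentrated just upstream of coding genes. Of the 2712 summits, 1375 (50.7%) lay within 500 bp of a coding 5' end, against a mean of 19.2% and a maximum of 21.3% over random placements (permutation p = 0.000999, the smallest possible). The median distance of nuclear summits to the nearest coding 5' end was 484 bp, and 1650 bp for random positions. Of the 1354 nuclear summits within 500 bp, 1171 (86.5%, 95% interval 84.6 to 88.2) lay upstream of the nearest coding 5' end, against a mean of 47.5% over random placements (permutation p = 0.000999, the smallest possible; chosen after seeing the data). By annotation, 60.4% of the 2683 nuclear summits were intergenic, 17.4% in introns, 9.99% in noncoding exons, 4.96% in coding exons, 3.50% in 3' untranslated regions and 3.32% in 5' untranslated regions.

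**Figure D2:**
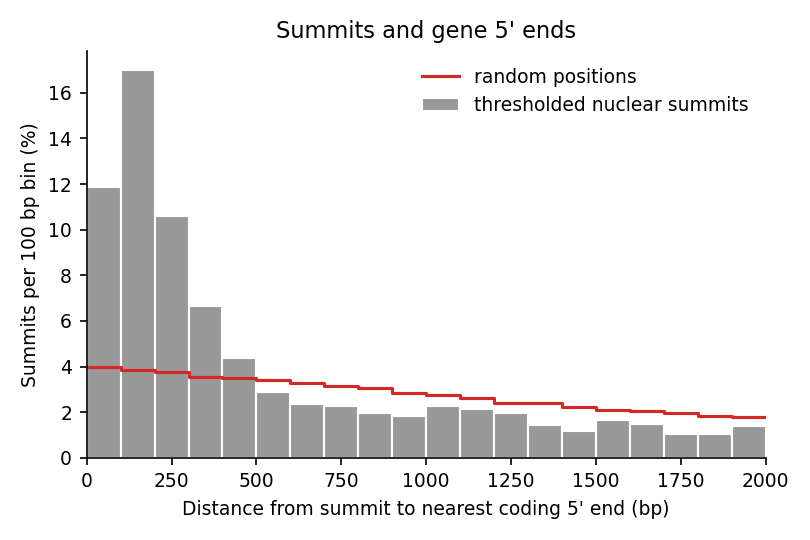
Distance from each thresholded nuclear summit to the nearest coding 5' end in bp (x axis, bins of 100 bp up to 2000 bp) against the share of summits in percent (y axis); grey bars are the 2683 nuclear summits and the red line is random positions on the same chromosomes. Summits exceed random positions in each bin below 500 bp, and the medians are 484 and 1650 bp.

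Bound genes were fewer on X than on autosomes, and a smaller share of X summits lay at coding 5' ends. In total 1719 of 19973 nuclear coding genes (8.61%, 95% interval 8.23 to 9.0) were bound; the count was 897 at a distance of 200 bp, and 1103 with the 1356 strongest peaks. On X, 111 of 2731 genes were bound (4.06%), against 1608 of 17242 (9.33%) on the autosomes (odds ratio 0.412, Fisher's exact p = 4.71e-23). Chromosomes III (14.5%) and I (13.3%) had the highest shares and V (5.57%) the lowest autosomal share. Only 102 of 377 X summits (27.1%, 95% interval 22.8 to 31.8) were within 500 bp of a coding 5' end, against 1252 of 2306 autosomal ones (54.3%, 52.3 to 56.3; odds ratio 0.312, Fisher's exact p = 2.94e-23; this comparison was chosen after seeing the data). Autosomal genes in the central 50% of the chromosome length were bound slightly more often (964 of 9597) than those in the outer parts (644 of 7645, 8.42%; odds ratio 1.21, Fisher's exact p = 0.000274). That difference was not past the threshold at a distance of 200 bp (exact p = 0.128), or with only the peaks among the strongest of both replicates (p = 0.0720).

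**Figure D3:**
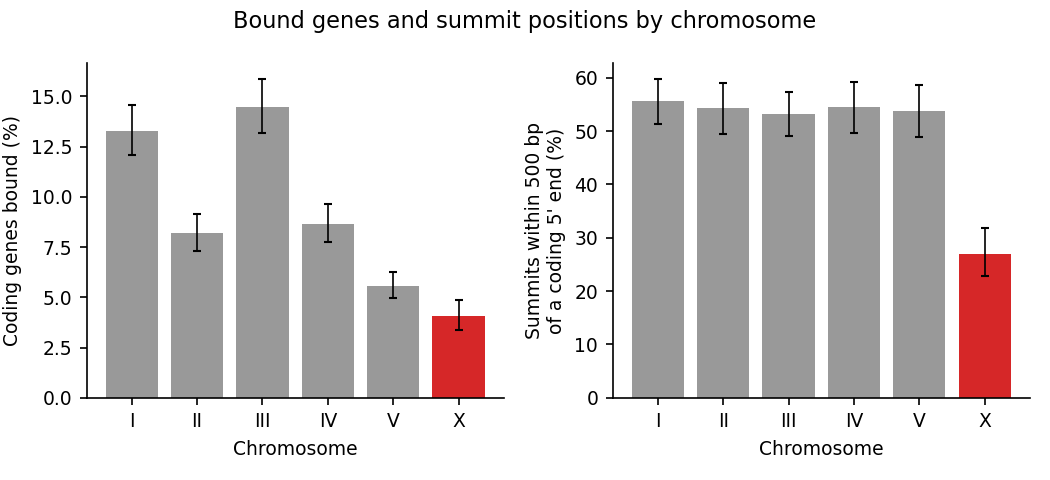
Left, share of coding genes with a summit within 500 bp of the 5' end; right, share of summits within 500 bp of a coding 5' end, both in percent per nuclear chromosome, with 95% Wilson intervals. X (red) has 4.06% of genes bound and 27.1% of summits at 5' ends, below each autosome in both plots.

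Genes of the DREAM complex itself were bound at 7 of 8 members (adjusted p = 9.39e-07, Fisher's exact test). The strongest was lin-54, with a signal of 731 at chromosome IV 13240527 to 13240850, a summit that lies 369 bp from lin-54 and 24 bp from the ribosomal gene rpl-12. Signals were 439 at lin-53, 394 at the E2F gene efl-1, 348 at lin-9, 236 at lin-35, 79.4 at the DP gene dpl-1 and 65.7 at lin-52, and lin-37 was unbound. The lin-35 summit was 167 bp upstream of the gene, at chromosome I 5807422 to 5807674. Of the genes that supplied parts of the transgene, lin-35 and pie-1 (signal 48.5) were bound and puf-5 and unc-119 were not. These 2 of 4 were not past the threshold (adjusted p = 0.0621, Fisher's exact test), but 3 of 4 from replicate 1 alone were (adjusted p = 0.00320, exact). The list also passed at 200 bp (adjusted exact p = 0.0250), with the nearest 5' end only (0.0417), and with the peaks among the strongest of both (0.0334). The lists do not separate the transgene's copy of a sequence from the chromosomal one.

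Cell cycle and genome maintenance genes were bound more often than other genes. In DNA replication 22 of 38 genes were bound, 6.73-fold over the average of all coding genes (adjusted exact p = 1.37e-13); the strongest were top-2, encoding topoisomerase II (signal 464), the sliding clamp gene pcn-1 (427), ctf-4 (353) and the clamp loader gene rfc-4 (297). In cell cycle and mitosis 22 of 54 were bound (4.73-fold, adjusted exact p = 9.30e-10), led by the kinase gene wee-1.3 (signal 302), the kinetochore gene knl-3 (290), the condensin gene hcp-6 (272) and the securin gene ify-1 (204). In DNA repair 11 of 31 were bound (4.12-fold, adjusted exact p = 7.60e-05), led by polh-1 (signal 239), the BRCA1 orthologue brc-1 (233), chk-1 (162) and mrt-2 (161). Among histone modifiers 7 of 22 were bound (3.70-fold, adjusted exact p = 0.00407), including mes-2, a histone H3 lysine methyltransferase gene (signal 264), mrg-1 (202), set-2 (185) and ash-2 (175); this list was not past the threshold at 200 bp (adjusted p = 0.135). Of the 71 bound genes chosen by the naming rule, 35 share their summit with another coding 5' end, which is nearer for 16; neighbours are named here and below after their values were seen. Nearer neighbours are npp-3 for top-2, eef-1G for ctf-4, let-630 for hcp-6, rps-22 for polh-1, spcs-2 for mrg-1 and Y17G7B.20 for ash-2; rfc-4 shares its summit with eef-1A.1 and ify-1 with rpl-22.

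Housekeeping genes were also bound more often than other genes. Of 78 cytosolic ribosomal protein genes 62 were bound (79.5%, 9.24-fold, adjusted exact p = 3.17e-50), with 16 of 33 proteasome genes (5.63-fold, adjusted p = 1.05e-08) and 20 of 70 mitochondrial ribosomal protein genes (3.32-fold, adjusted p = 3.40e-06). The ribosomal protein count depends on the distance: 8 of 78 were bound at 200 bp (2.28-fold, adjusted exact p = 0.0471), and 39 of 78 with the nearest 5' end only (7.45-fold). The proteasome genes rpn-11 (signal 312), rpn-3 (226), pbs-1 (164) and rpn-2 (129) and the mitochondrial ribosomal genes mrpl-47 (285), mrpl-55 (217), mrps-16 (216) and mrpl-28 (190) led their lists. Bound ribosomal protein genes had a median signal of 117, against 85.2 for other bound genes (permutation test, adjusted p = 0.0182 over 6 lists); the other 5 lists tested did not differ at that threshold.

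Germline lists gave mixed counts. P granule and small RNA genes were bound at 8 of 43 (2.16-fold, adjusted exact p = 0.0481), led by rde-4 (signal 160), mut-15 (128), ekl-1 (110) and rde-10 (107); the mut-15 and ekl-1 summits are nearer to fib-1 and prpf-4. This call was lost from either replicate alone (adjusted exact p = 0.185 and 0.240), and with the peaks among the strongest of both (0.155). It was also lost with the 1356 strongest peaks, at 200 bp, and with the nearest 5' end only. Oocyte and germline RNA regulators were not past the threshold, with 4 of 32 bound (adjusted exact p = 0.418), among them spn-4 (signal 139) and atx-2 (127). Replicate 1 alone gave 12 of 32 (4.84-fold, adjusted exact p = 7.34e-06) and replicate 2 alone 5 of 32 (adjusted p = 0.244). Of these genes 8 were bound in replicate 1 alone and 1 in replicate 2 alone (exact McNemar test p = 0.0391, adjusted p = 0.299 over 23 comparisons), which compares 2 libraries only. Cytosolic ribosomal protein genes differed the other way, with 1 and 8 (exact p = 0.0391, adjusted p = 0.299). Only the comparison of all coding genes passed, with 419 bound in replicate 1 alone and 563 in replicate 2 alone (adjusted exact p = 0.000112). Meiosis genes were bound at 1 of 34, him-17 (signal 47.7), and sperm genes at 2 of 74, spe-39 (139, the same summit as spn-4) and spe-48 (110); neither list passed (adjusted p = 0.418 and 0.126, Fisher's exact tests). For meiosis genes replicate 1 alone gave 4 of 34 (1.52-fold) and replicate 2 alone 1 of 34 (0.347-fold), with 0 bound in both, so its direction is not settled. The other synMuv genes, 4 of 17 with mys-1 (signal 227) and epc-1 (91.8), gave an adjusted p of 0.0771 (Fisher's exact test), and passed from replicate 2 alone with 6 of 17 (adjusted p = 0.00439, exact), within 1000 bp (0.000431), and with the nearest 5' end only (0.0417). Dosage compensation genes were bound at 2 of 10, sdc-2 (signal 141) and mix-1 (132; adjusted p = 0.272, Fisher's exact test), and passed within 1000 bp (0.0273).

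Chemoreceptor, neuropeptide, cuticle collagen and histone genes were bound less often than other genes. Chemoreceptors were bound at 9 of 1364 (0.660%, 0.0767-fold, adjusted exact p = 6.60e-41). That list was drawn by name prefix, so it can hold genes of other function; among those bound were sri-5 (signal 373) and srr-10 (157, nearer to clic-1). No neuropeptide gene of 140 was bound (adjusted exact p = 1.54e-05, upper limit 2.14%); the count was 1 from replicate 1 alone, 2 from replicate 2 alone and 3 within 1000 bp, each past the threshold. Cuticle collagens were bound at 4 of 156 (0.298-fold, adjusted exact p = 0.00748), col-38 (signal 212), col-85 (118.5), col-71 (91.6) and col-72 (82.8), with the col-38 and col-71 summits nearer to rpl-5 and Y49F6B.2; the call was lost from replicate 1 alone (adjusted p = 0.111), with the peaks among the strongest of both replicates (0.225), and with the 1356 strongest peaks (0.192). Histone genes were bound at 1 of 72, his-37 (signal 302; adjusted exact p = 0.0362), a call lost from either replicate alone (adjusted p = 0.0731 and 0.0511). It was also lost with the 1356 strongest peaks, the peaks among the strongest of both, either other distance and the nearest 5' end only. Reads of near-identical histone copies may be assigned to more than 1 place, so this count is uncertain. Neuronal genes (3 of 30, with ric-19 at 76.9 and unc-18 at 50.8), muscle genes (2 of 20, unc-60 at 102 and unc-45 at 95.7) and intestine genes (0 of 19, upper limit 15.8%) were not past the threshold (adjusted exact p = 0.741, 0.721 and 0.442). From single replicates, 2 neuronal genes were bound in replicate 1 and 4 in replicate 2, with 0 in both. In all, 13 of 22 lists passed, 9 higher and 4 lower.

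**Figure D4:**
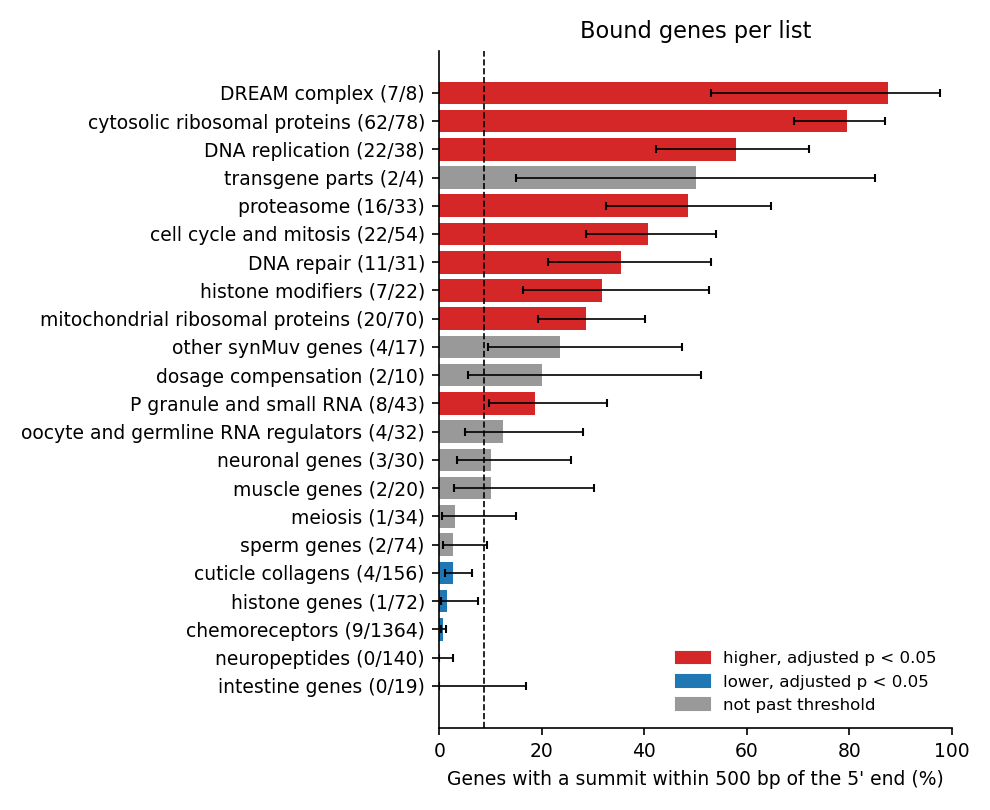
Share of genes with a summit within 500 bp of the 5' end (x axis, percent) for each of the 22 lists (y axis, bound over total genes); error bars are 95% Wilson intervals, the dashed line is the average of all coding genes (8.61%), red and blue bars are lists higher or lower at an adjusted p under 0.05 and grey bars are the rest. The DREAM complex (7 of 8) and cytosolic ribosomal proteins (62 of 78) have the highest shares, and neuropeptides (lower) and intestine genes (not past the threshold) have none.

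The E2F site, the sequence recognised by the E2F and DP partners of DREAM, was more frequent at bound promoters, and so was its reversed form. The word TTSSCGC, with S for C or G, occurred in 335 of 1354 windows of 100 bp on each side of the summit (24.7%, 95% interval 22.5 to 27.1), against 89 of 1354 control windows (6.57%; 3.76-fold, Fisher's exact p = 2.17e-40, adjusted p = 1.30e-39 over 6 motifs). The enrichment was 6.0-fold with the 1356 strongest peaks and 6.24-fold in narrower windows of 50 bp on each side. The reversed word was in 14.4% of windows and 2.73% of controls (5.27-fold, exact p = 2.73e-29), and was enriched 5.23-fold and 7.0-fold in those settings. Peak windows had a mean GC content of 40.2% and controls 34.5%. With controls matched on GC content the enrichment was 2.80-fold for the E2F site and 2.92-fold for its reverse. It was thus not larger there than that of the composition control. Which word had the larger fold varied with the setting, and random control windows were drawn once per setting. The E2F site and its reverse gave 4.64-fold and 4.43-fold with merged peaks, and 4.21-fold and 4.51-fold without ribosomal protein promoters. Replicate 1 alone gave 3.92-fold and 3.67-fold, and replicate 2 alone 4.74-fold and 4.0-fold. The CHR element TTYGAA, with Y for C or T, which the LIN-54 subunit recognises, was in 55.2% of windows and 56.9% of controls (0.971-fold, exact p = 0.416, raw and adjusted), while its reverse was depleted (0.698-fold, p = 2.21e-09). Against controls matched on GC content the CHR element was 1.29-fold enriched (exact p = 1.47e-10) and its reverse 0.838-fold (p = 0.00609). The GAGA repeat was 2.12-fold enriched (exact p = 4.37e-21), 1.55-fold with GC matching, and the E-box was not past the threshold (1.37-fold, p = 0.117), except in the narrower windows (2.11-fold, p = 0.00794). Both DREAM motifs were more frequent in stronger peaks: from the strongest to the weakest signal quartile, the E2F site was in 32.2%, 28.9%, 23.7% and 14.2% of windows and the CHR element in 70.5%, 55.2%, 48.5% and 46.7%. The intervals for the strongest and weakest quartiles were 27.4 to 37.3% and 10.9 to 18.3% for the E2F site, and 65.4 to 75.1% and 41.5 to 52.1% for the CHR element. The reversed E2F site ran from 20.1% to 10.7% and the reversed CHR element from 28% to 22.8%. For the CHR element only the strongest quartile was above the 56.9% of the main controls. Each quartile was above the 42.9% of controls matched on GC content, but the interval of the weakest includes that value.

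**Figure D5:**
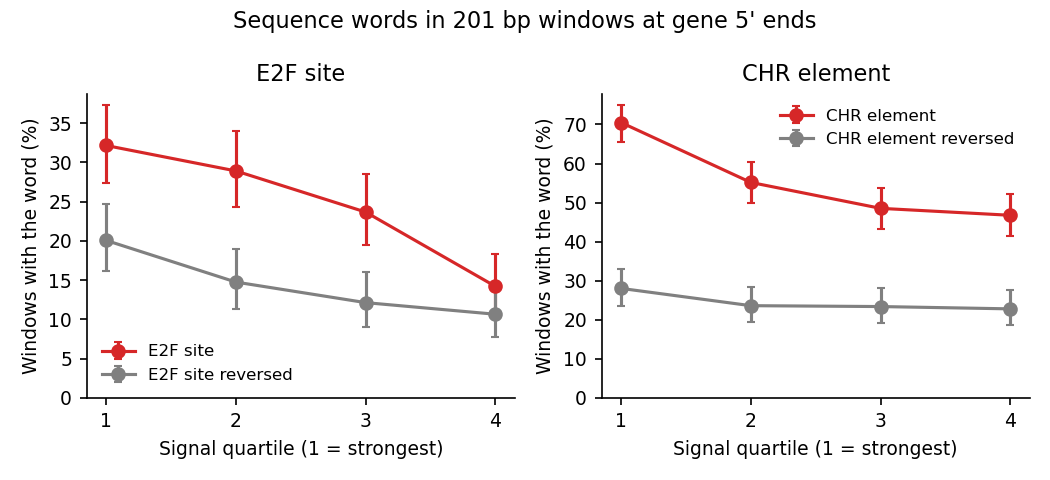
Share of windows of 100 bp on each side of the summit at gene 5' ends that hold the word (y axis, percent) by quartile of peak signal (x axis, 1 is the strongest), for the E2F site (left) and the CHR element (right); red is the motif, grey its reversed form, and bars are 95% Wilson intervals. The CHR element falls from 70.5% to 46.7% and the E2F site from 32.2% to 14.2%, while the reversed words lie lower in each quartile. The reversed words are also less frequent in control windows (2.73% against 6.57% for the E2F site, 35.0% against 56.9% for the CHR element).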

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

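The tests of the recruitment word, with summits or intervals counted, of replicate support for the X peaks and of noncoding genes were chosen after the result was seen; those of repeated sequence and of the E2F site at tRNA genes were stated before.

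The mitochondrial genome, whose genes are in no gene list, bound gene count or motif comparison, held 29 thresholded peaks; its summits are in the replicate comparison and in the share at coding 5' ends, which was 50.5% without them. Of these, 28 share 1 interval of 13385 bp that covers 97.0% of its 13794 bp, and the strongest has a signal of 8256.

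A set of 12 X peaks over 500 bp wide, which add no bound gene because none has a coding 5' end within 500 bp, drew attention by its strength, with a median signal of 546 against 61.9 for other X peaks away from coding genes. They fall in 11 intervals, and 6 of the 30 strongest nuclear peaks are X peaks without a coding 5' end; the autosomes had 8 peaks as wide. Exactly repeated sequence around their summits is argued against. Within 100 bp of the summits, a median of 0% of the 36-base words occur more than once in the genome, and the highest share is 11.4%. The rest of these peaks, of median width 633 bp, and near-identical copies were not examined. Of the 12, 11 were among the strongest 2712 of both replicates, so these 11 had signal in both libraries. Their strength made that likely beforehand: of the 678 strongest thresholded peaks, 658 (97.1%) were among the strongest 2712 of both. The count is therefore not a separate test of signal in a single library. A hypothesis is that these are recruitment sites of the dosage compensation complex: the core word GCGCAGGG was within 250 bp of 8 of 12 summits, against 2 of 102 X summits at coding 5' ends (odds ratio 100, Fisher's exact p = 3.78e-08), and the reversed word was near 0 of 12. With each interval counted once it was near 7 of 11 (odds ratio 87.5, exact p = 2.88e-07). Whether LIN-35 itself is there, or these sites are recovered in any ChIP, stays open, since no control or other factor was analysed here.

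Some nuclear peaks away from coding 5' ends lay at tRNA genes, which are in no gene list. Of 1329 such summits, 150 were within 100 bp of a tRNA gene, against a mean of 2.36 over random placements (permutation p = 0.000999, the smallest possible). These summits do count in the shares of summits at coding 5' ends, also in that of X against the autosomes. Over all thresholded summits, also those at coding 5' ends, 190 of 612 tRNA genes had a summit within 100 bp. Of the 150 summits, 81 were on X, which has 276 tRNA genes and 275 summits away from coding 5' ends. The E2F site was in 8.0% of windows at these peaks and 24.7% of windows at coding 5' ends (odds ratio 0.265, Fisher's exact p = 6.39e-07), which is consistent with occupancy that does not need that site; the reversed word was also less frequent there (odds ratio 0.291). Reads shared between tRNA copies cannot be told apart from binding to each copy: the median share of repeated 36-base words was 29.2% at tRNA genes with a summit and 28.9% at those without (permutation p = 0.308 for the means), and how multiply mapping reads were treated is not given in the sources used here.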

How the results depend on the processing

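Of 309 values under alternatives, 270 stayed on their side of the threshold, or within the limits set for values without a test. Values not past the threshold could change direction and still count among these, as meiosis genes did from replicate 1 alone. In an alternative, 14 list or motif values not past the threshold passed it, 4 of them for the CHR element with a changed direction. Peaks among the strongest of both replicates is an alternative chosen after seeing the data. The peak count was 1356 for the stronger part of the list and 1445 among the strongest of both replicates, and bound genes numbered 1103 and 1094 there and 897 at 200 bp; the smaller lists and shorter distance are themselves the reason. The rank correlation was 0.574 with summits within 100 bp. The odds ratio of the chromosome centre was 1.12 at 200 bp and 1.13 among the strongest of both replicates, not past the threshold.

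P granule and small RNA genes lost their call at 2.11-fold in that stronger part, 1.04-fold at 200 bp, 2.08-fold with the nearest 5' end, 2.12-fold among the strongest of both, and 1.65 to 1.80-fold from single replicates. Histone genes lost it at 0.251, 0.309, 0.207 and 0.254-fold in the same settings, at 0.509-fold within 1000 bp, and at 0.164 to 0.179-fold from single replicates. Collagens lost it at 0.464-fold in that stronger part and 0.468-fold among the strongest of both, and ranged from 0.303 to 0.497-fold in single replicates. Histone modifiers lost it at 200 bp (3.04-fold). The CHR element, not past the threshold in the main comparison, was enriched 1.10-fold in that stronger part, 1.13-fold against windows 500 bp away and 1.29-fold with GC matching, and ranged from 0.988 to 1.08-fold in single replicates; only replicate 1 alone was past the threshold (exact p = 0.0255). The cause of these changes was not tested, except that GC matching removes a GC difference. The depth of the libraries was not analysed here, so weak peaks missed for lack of reads cannot be counted.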

Other observations

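The family and noncoding comparisons, and the motif comparisons other than those of the E2F site, were chosen after the data were seen; the E2F comparisons between gene groups were stated before they were run.

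Gene families defined by their name prefix were also compared, all 240 with at least 8 coding genes. Of these, 19 were bound more often and 12 less often than other genes (Fisher's exact test, Benjamini-Hochberg adjusted). Several of them, such as rpl, rps, mcm, mrpl, rpn, str, srh, srx, srw, srz, nlp and col, hold genes of the lists above. Their results repeat those lists and add no separate evidence. Nuclear pore genes (npp) were bound at 13 of 26 (5.81-fold, adjusted exact p = 2.91e-06), with npp-3 and npp-19 strongest. SR splicing factor genes (rsp) were bound at 6 of 8 (8.71-fold, adjusted p = 0.000258, exact test), as were 6 of 8 mcm genes. Chaperone and translation families followed, with 11 of 29 dnj genes (4.41-fold, adjusted p = 0.000359), 10 of 25 eif genes (4.65-fold, adjusted p = 0.000463) and 5 of 8 cct chaperonin genes (7.26-fold, adjusted p = 0.00297, exact test). Excesses with larger adjusted p-values were seen at 7 of 20 vha genes of the vacuolar ATPase, 6 of 15 cox genes, 5 of 11 rpb genes of RNA polymerase II and 5 of 11 ints genes of the Integrator complex (4.07 to 5.28-fold, adjusted p from 0.0111 to 0.0139). Families that passed as bound less often were large: none of 193 str genes or 170 fbxa genes was bound (upper limits 1.55% and 1.76%), 3 of 240 clec genes and 7 of 269 nhr nuclear receptor genes (0.302-fold, adjusted exact p = 0.00164). Size limits this test: the srg and srt families did not pass with 0 of 61 genes bound in each (adjusted exact p = 0.0639).

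Other small structured RNAs were near peaks too. Among the 1329 nuclear summits away from coding 5' ends, 54 were within 100 bp of a snoRNA gene (mean of random placements 1.47) and 16 of a snRNA gene (mean 0.50; both permutation p = 0.000999, the smallest possible). With tRNA genes, these account for 220 summits (16.6%). Near miRNA genes there were 4 summits, against a random mean of 1.035 (permutation p = 0.0170, adjusted p = 0.0255). Fewer summits than at random were near pseudogenes (13, random mean 51.6) and piRNA genes (3, random mean 25.39).

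Ribosomal protein promoters were among the strongest peaks, and a candidate explanation is occupancy that does not need the E2F site. The E2F site was in 7 of 60 windows at ribosomal protein genes (11.7%, 95% interval 5.77 to 22.2), against 328 of 1294 other windows at coding 5' ends (odds ratio 0.389, Fisher's exact p = 0.0142, adjusted p = 0.0255 over 9 motif comparisons). The reversed word did not differ at the threshold (16.7% and 14.3%, exact p = 0.574). General recovery of active promoters stays open, since no control or expression values were analysed here.

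Cell cycle genes differed from housekeeping genes in the same respect. The E2F site was in 33 of 54 windows at cell cycle, replication and repair genes (61.1%, 95% interval 47.8 to 73.0) and in 9 of 35 at proteasome and mitochondrial ribosome genes (25.7%, 14.2 to 42.1; odds ratio 4.54, Fisher's exact p = 0.00123, adjusted p = 0.00370). The reversed word was in 7 of 54 and 7 of 35 (exact p = 0.388), and the CHR element in 85.2% and 65.7% (p = 0.0397, adjusted p = 0.0596). LIN-35 may be recruited differently at the 2 kinds of bound promoter; this is a hypothesis, and no binding of E2F or DP was analysed here to test it.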
